A study of Drosophila melanogaster with 12 samples.

How the data were processed

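Total RNA from whole bodies was extracted with TRIzol and sequenced on a BGISEQ-500, per the labels' protocols. The submitters' processing notes name FastQC 0.11.9, STAR, RSEM 1.3.3, edgeR 3.12 and the dm6 genome build, without the settings or the role of each. The authors deposited 1 table of FPKM values with 2 decimals for 14001 genes in 12 libraries. How reads shared between near-identical genes were divided, and whether strand was used, is not given in the sources used here. The table holds 205 genes whose values equal those of another gene, and results for near-identical copies are uncertain. A file of FPKM cannot carry a count test, so the count model planned before the data were examined was replaced by the fallback planned with it.

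Gene names came from an Ensembl annotation of the dm6 assembly, which matched 13777 of 14001 identifiers, and coordinates are from the same annotation. Where a gene has a single annotated transcript, low FPKM values are whole multiples of what 1 read is worth. From 614 to 768 such genes per library, 91.5 to 94.7% of values lay within 0.2 of a whole read, where 40% are expected by chance, and this gave 11220000 to 12180000 reads per library. Replicates differed by more than sampling noise in every group, with chi-square per degree of freedom of 7.37 to 102.84, and all 12 libraries were used. Libraries were assigned to groups by the labels, as 3 replicates each of sensitive larvae, resistant larvae, sensitive adults and resistant adults.

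Each stage was fitted to its own 6 libraries, and the difference of the strain effect to all 12. Genes were kept where at least 3 libraries of the fit were at 1 FPKM or more. Values were taken as log2(FPKM + 1), so fold changes are on that scale and understate those of low genes. The test was limma 3.58.1 with a mean-variance trend and robust empirical Bayes in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No scaling beyond the FPKM was applied in the main fits. Median-of-ratios, upper-quartile and common-total scaling were computed by hand as alternatives, with the filter applied to the unscaled values. The order of filter and scaling was set after a first look at the scaled counts.

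Gene lists, 33 in all, were fixed before the data were examined, and those with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. The lists were ligand-gated chloride channels, nicotinic receptors, P450, glutathione transferases, UDP-glycosyltransferases, carboxylesterases, ABC transporters, oxidative stress, heat shock, antimicrobial, lysozymes, digestive proteases, carbohydrases, cuticle, lipid metabolism, ecdysone response, salivary glue, larval serum, yolk and eggshell, female germline, accessory gland, testis, dosage compensation, muscle, photoreceptor, neuronal, hemocyte, odorant-binding, chemoreceptors, Malpighian tubule, ribosomal, respiratory chain and mitochondrially encoded genes. Named genes followed a rule fixed at the same time: GluClalpha, Rdl, Mdr49, Mdr50 and Mdr65; the 6 largest rises and 6 largest falls per stage at an average log2(FPKM + 1) of 1 or more with groups that do not overlap; up to 2 rising and 2 falling members of the detoxification, cuticle and called lists; 4 genes in each direction of the difference between stages; and 5 genes in each direction called in both stages. The rule spoke of log2 CPM, read here as log2(FPKM + 1). The text names part of the list members the rule takes.

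The steps were tested on simulated FPKM drawn from the means of the sensitive libraries and the estimated depth of each library. In these, 200 genes were changed, 100 of them 2-fold and 100 of them 4-fold. The larval fit of 10719 genes recovered 84 and 100 of these, and 2.6% of its calls were unchanged genes. The adult fit of 11357 genes recovered 63 and 99, with 4.1% unchanged. The fit of the difference, on 11983 genes, recovered 26 and 97, with 3.1% unchanged. The simulated genes varied independently, so the list test, which recovered 3 of 3 lowered lists with 0 others called in each stage, was not tested against correlated genes. All simulated genes of a stage had the same dispersion, and no shift of all genes was added. The shares of unchanged genes among the calls therefore need not hold for the real libraries.

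Further alternatives were no filter, a mean FPKM of at least 5, a pseudocount of 0.1, the replicate number as a block, 1 fit of all 12 libraries, stricter thresholds, and each library left out in turn. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.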

Results

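Gene expression was measured by RNA sequencing in whole bodies of *Drosophila melanogaster* from a strain sensitive to avermectins, a class of insecticides that act on glutamate-gated chloride channels, and from a strain resistant to them. Each strain was sampled as third-instar larvae and as adults, which gave 4 groups of 3 libraries. The values are FPKM, fragment counts divided by transcript length and by the library's total, for 14001 genes. The steps between the low FPKM values correspond to an estimated 11220000 to 12180000 reads per library, and 12997 to 13452 genes were above 0 in a library. The 20 most abundant genes took 25.35 ± 1.29% of all FPKM in sensitive larvae, 22.35 ± 2.21% in resistant larvae, 10.88 ± 0.24% in sensitive adults and 11.24 ± 1.3% in resistant adults (SD, n = 3 per group). Values after a mean are SDs over 3 libraries throughout, and coordinates are on the dm6 assembly. The labels do not say whether the replicates were separate cultures, nor do they give the sex or exact age of the animals, so the p-values measure the spread between these libraries, which may be technical.

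Stage separated the libraries far more than strain did. The first principal component of the 1000 most variable genes held 91.3% of the variance and separated larvae from adults, the second held 3.7% and separated the larval strains, and the third held 2.6% and separated the adult strains. On the second component, resistant larvae replicate 3 lay at -8.91, between the other resistant larvae at -29.35 and -27.18 and the sensitive larvae at 17.75 to 25.78. Pearson correlations of log2(FPKM + 1) across genes were 0.891 to 0.954 between the larval strains, 0.916 to 0.951 between the adult strains and 0.591 to 0.688 between the stages. Within groups the lowest was 0.94.

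The first comparison asked which genes differ between the strains in third-instar larvae. Among the genes called, most of those for cuticle, glutathione transferases, muscle and the respiratory chain were lower in resistant larvae. Cpr47Eg, a structural cuticle gene, was at 43.57 ± 74.55 FPKM in resistant and 1560.24 ± 600.27 FPKM in sensitive larvae. GstD2, a glutathione S-transferase, fell from 147.90 ± 35.22 to 4.55 ± 2.28 FPKM. Cht5, a chitinase of cuticle turnover, rose from 4.04 ± 0.43 to 20.61 ± 5.48 FPKM. In limma, 6484 of 11055 genes passed an FDR of 0.05, 5396 higher and 1088 lower in resistant larvae.

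The median log2 fold change of the larval genes was 0.49, so most genes read higher in the resistant strain. After median-of-ratios scaling, the one meant by scaling from here on, 3355 genes passed, 1251 higher and 2104 lower, and the share of higher calls went from 83.2% to 37.3%. All 1251 genes higher after scaling and 1086 of the lower ones had the same call without scaling, and no gene was called in opposite directions. "Rose" and "fell" are therefore written of single genes only where both fits called them. Groups did not overlap in 65.3% of larval genes, where chance gives 10%.

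**Figure D1:**
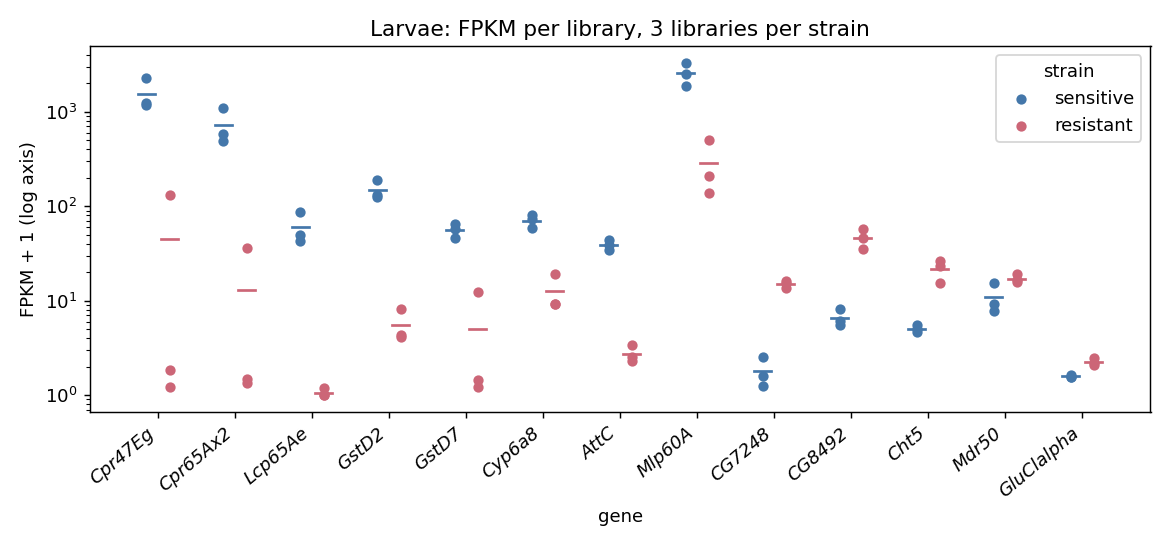
FPKM + 1 (log axis) of named genes in the 3 sensitive and 3 resistant larval libraries; points are libraries and short lines are group means. Lcp65Ae lay at 59.17 ± 23.98 FPKM in sensitive and 0.06 ± 0.10 FPKM in resistant larvae, while Mdr50 and GluClalpha lost their call after scaling (log2 fold changes of 0.20 and 0.24).

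Of 68 tested cuticle genes, 35 were lower and 15 higher, also 35 and 15 when adjusted over the list alone, but 40 and 6 after scaling. Lcp65Ae (3L:6137583-6138118) fell by 5.76 on the log2 scale (adjusted p 9.92e-07, limma). Cpr65Ax2 and Lcp65Ag3 also fell, but both belong to clusters of near-identical copies whose shared reads could not be assigned with certainty. Cpr49Ac rose from 662.88 ± 183.42 to 3019.12 ± 1098.85 FPKM, and Cpr76Bc rose from 0.61 ± 0.18 to 4.13 ± 1.25 FPKM. The calls of Cpr47Eg, Cpr65Ax2 and Lcp65Ag3, whose resistant SDs exceeded their means, ended when any of 5, 4 and 4 of the 6 libraries was left out, with adjusted p of 0.09135 to 0.1074, 0.05114 to 0.06581 and 0.05779 to 0.073. The replicate block also ended that of Cpr47Eg (adjusted p 0.05369). The ecdysone list, genes of the moulting hormone, had 16 higher and 5 lower of 26 members, which turned to 5 higher and 6 lower after median-of-ratios scaling. Its members ImpE1, at 10.62 ± 4.24 against 1.94 ± 0.68 FPKM, and ImpE2, at 244.57 ± 42.69 against 58.75 ± 14.76 FPKM, rose. They are named after their values were seen. Camera did not call the list (adjusted p 0.9096). Of 13 salivary glue genes, 2 were higher and 0 lower, against 0 higher and 2 lower after scaling.

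Of 33 tested glutathione transferases, 18 were lower and 1 higher, also 18 and 1 adjusted over the list alone and 25 and 0 after scaling, but camera with an estimated correlation did not call the list (adjusted p 0.2613). GstD7 fell from 54.95 ± 9.26 to 4.04 ± 6.42 FPKM, a call that ended when any of 5 of the 6 libraries was left out (adjusted p 0.06211 to 0.08137). The higher member, GstO1, with a log2 fold change of 0.44, reversed to -0.10 after scaling. Of 73 cytochrome P450 genes, 15 were higher and 19 lower, or 13 and 18 adjusted over the list alone, and 2 and 28 after scaling. Cyp304a1 rose from 9.67 ± 1.14 to 34.22 ± 4.62 FPKM, while Cyp6a8 fell from 69.42 ± 11.25 to 11.60 ± 5.84 FPKM and Cyp6a2 fell from 10.85 ± 0.24 to 2.45 ± 2.71 FPKM. Of 25 UDP-glycosyltransferases, 11 were higher and 3 lower, and 3 and 3 after scaling. Ugt36D1 rose by 1.47 and Ugt35B1 fell by 1.80 on the log2 scale. The calls of Cyp6a2 and Ugt35B1 ended without 2 and 3 of the libraries in turn (adjusted p 0.05204 to 0.0534 and 0.06412 to 0.08024). Of 24 carboxylesterases, 8 were higher and 3 lower, which turned to 3 higher and 6 lower after scaling, with Est-P at 34.45 ± 7.59 against 9.37 ± 1.19 FPKM and Est-6 at 1 ± 0.64 against 6.34 ± 1.68 FPKM. Of 35 ABC transporters, 18 were higher and 2 lower, which turned to 5 higher and 6 lower after scaling. Atet rose from 5.27 ± 2.22 to 17.39 ± 2.95 FPKM and st, an eye pigment transporter, fell from 4.81 ± 1.33 to 1.52 ± 0.25 FPKM.

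Of 84 nuclear respiratory chain genes, 57 were lower and 9 higher, or 59 and 11 adjusted over the list alone and 62 and 1 after scaling, and ATPsynF fell from 1025.04 ± 236.87 to 295.39 ± 112.27 FPKM. Of 23 muscle genes, 14 were lower and 1 higher, or 18 and 0 after scaling, and Mlp60A fell from 2556.63 ± 708.79 to 284.56 ± 195.72 FPKM. Of 28 antimicrobial genes, 12 were lower and 7 higher, or 12 and 2 after scaling. AttC, an antibacterial peptide, fell from 37.87 ± 4.83 to 1.72 ± 0.55 FPKM. PPO2, a prophenoloxidase of melanization, fell from 84.51 ± 13.26 to 12.87 ± 3.73 FPKM, and PPO1 fell from 60.08 ± 9.71 to 10.35 ± 4.32 FPKM. Men, malic enzyme, fell from 194.12 ± 17.98 to 68.14 ± 9.46 FPKM and Pgd, of the pentose phosphate pathway, fell from 180.16 ± 46.50 to 59.96 ± 11.52 FPKM. Further falls were Obp83g among odorant-binding proteins (by 3.24 on the log2 scale), tobi among carbohydrases (by 2.68), apolpp among lipid genes (by 1.85), Uro among Malpighian tubule genes (by 1.48) and RpL8 among ribosomal proteins (by 1.06). Outside the lists, CG17105 fell from 520.77 ± 45.82 to 7.13 ± 1.43 FPKM and CG11350 from 355.47 ± 106.20 to 7.63 ± 12.75 FPKM, the latter a call that ended without any of 3 libraries (adjusted p 0.05001 to 0.06247). CG7248 rose from 0.80 ± 0.66 to 14.00 ± 1.26 FPKM, CR31054 from 0.19 ± 0.33 to 8.19 ± 1.89 FPKM and CG8492 from 5.57 ± 1.43 to 45.15 ± 10.66 FPKM. CG3819 and CG6839 had log2 fold changes of 2.90 and 2.73, or 2.36 and 2.17 after scaling, where they were not called (adjusted p 0.1407 and 0.08255).

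Of 26 larval lists, camera called 15, all lower: P450, glutathione transferase, oxidative stress, antimicrobial, digestive protease, carbohydrase, cuticle, lipid, muscle, hemocyte, odorant-binding, Malpighian, ribosomal, respiratory chain and mitochondrially encoded genes. With an estimated correlation camera called 0, these 15 had adjusted p = 0.2613 to 0.7803, and 4 lists had an unadjusted p under 0.05. Fry, which tests against no change and was run without scaling, called 12, of which 4 were lower (glutathione transferase, oxidative stress, antimicrobial and cuticle) and 8 higher (UDP-glycosyltransferase, carboxylesterase, ABC transporter, heat shock, ecdysone, female germline, testis and neuronal). After scaling the medians of those 8 were 0.03, -0.14, 0.01, 0.46, 0.41, 0.26, 0.04 and 0.24, so the shift of all genes accounts for much of their rise, and camera called none of them. Fry did not call muscle, respiratory chain and P450 genes (adjusted p 0.05511, 0.0705 and 0.5791). The digestive protease and carbohydrase calls were lost after scaling (adjusted p 0.4971 and 0.271). The P450, odorant-binding and digestive protease lists had medians of 0.04, 0.03 and -0.005 although camera placed them below other genes, whose median was 0.49. Digestive proteases took 10.85% of FPKM in sensitive replicate 1 against 4.559 and 4.17% in the other sensitive larvae and 6.403 to 8.63% in the resistant ones. Of the 10 groupings of these 6 larval libraries, 6 gave as many called lists, so the number of lists does not set the strains apart. Of the 86 named genes called in larvae, 24 lost the call when at least 1 library was left out and 20 lost it after scaling. Genes that fell below the filter without a library, such as CR31054, Cpr76Bc and Lcp65Ae, were untested there and not counted as lost. The 24 is therefore a lower bound.

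The second comparison asked the same of adults. Among the genes called, those for cuticle, larval serum proteins, testis, accessory gland and muscle were higher in resistant adults, and most of those for digestive enzymes and antimicrobial defence were lower. Fbp1, a fat body gene, rose from 0.98 ± 0.17 to 45.56 ± 18.41 FPKM and Fbp2 rose from 1.63 ± 0.51 to 80.60 ± 39.11 FPKM. The trypsin gene gammaTry fell from 151.09 ± 69.66 to 7.39 ± 2.93 FPKM. In limma, 2309 of 11612 genes passed, 1850 higher and 459 lower, with a median log2 fold change of 0.02. After median-of-ratios scaling 1762 passed, 1283 higher and 479 lower. The groups did not overlap in 32.1% of genes, where chance gives 10%. The count rested on single libraries: it was 497 without resistant replicate 1, 951 without sensitive replicate 3 and 1225 without sensitive replicate 2.

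**Figure D2:**
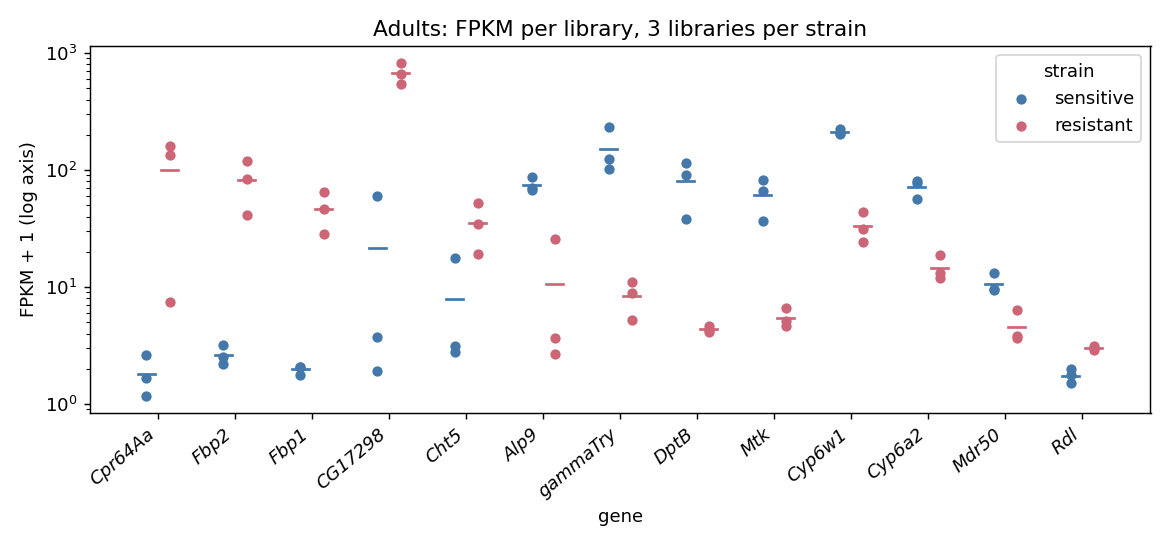
FPKM + 1 (log axis) of named genes in the 3 sensitive and 3 resistant adult libraries; points are libraries and short lines are group means. Fbp1 lay at 45.56 ± 18.41 FPKM in resistant against 0.98 ± 0.17 FPKM in sensitive adults; Cpr64Aa, Cht5 and Alp9 lost their call after scaling, with log2 fold changes of 4.91, 2.51 and -3.65.

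Of 66 cuticle genes, 23 were higher and 0 lower, or 28 and 2 adjusted over the list alone. The calls were fewer after scaling, 16 higher and 1 lower. Cpr64Aa was at 99.70 ± 81.87 against 0.82 ± 0.74 FPKM and Cpr64Ac at 40.23 ± 33.96 against 0.58 ± 0.17 FPKM, and neither was called after scaling, with log2 fold changes of 4.91 and 3.79 (adjusted p 0.06866 and 0.1169). The larval serum genes, storage proteins of the larval fat body, were higher in 3 of 4: Lsp1beta rose from 7.74 ± 1.17 to 51.10 ± 12.49 FPKM, and Lsp1alpha and Lsp1gamma rose by 1.97 and 2.55 on the log2 scale. These were named after their values were seen. CG17298 rose from 20.66 ± 32.67 to 672.29 ± 139.36 FPKM and CG34205 from 0.60 ± 0.97 to 34.99 ± 25.83 FPKM. CG17298 lost its call without sensitive replicate 3 or resistant replicate 2 (adjusted p 0.1134 and 0.08839), or with a replicate block (0.1791). Of 13 neuronal genes 7 were higher, and ple, tyrosine hydroxylase, rose from 6.5 ± 3.84 to 68.29 ± 36.61 FPKM.

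Testis genes were higher in 24 of 27, or 26 adjusted over the list alone, and accessory gland genes in 19 of 31, or 25, with 0 lower in either list. ProtA, a sperm chromatin gene, rose by 1.46 on the log2 scale, and Acp53C14c rose from 8.36 ± 3.68 to 38.99 ± 9.80 FPKM. Of 24 yolk and eggshell genes, 4 were lower and 20 not called, 2 were lower after scaling and 0 were called adjusted over the list alone. Yp1, a yolk protein gene, was at 2606.33 ± 680.33 against 5432.96 ± 510.63 FPKM, and its call was lost without any of 4 of the 6 libraries (adjusted p 0.06087 to 0.09081). Of 18 female germline genes none was called. Of 25 muscle genes, 18 were higher and 0 lower, or 11 and 0 after scaling, and TpnC41C rose from 81.24 ± 7.66 to 377.40 ± 81.87 FPKM. Among respiratory chain genes 12 of 86 were higher, or 8 after scaling, with COX6CL at 24.69 ± 2.33 against 9.75 ± 1.82 FPKM (adjusted p 0.05334 without resistant replicate 1), and among photoreceptor genes 5 of 20, or 2 after scaling, with Galphaq at 49.36 ± 7.70 against 17.90 ± 2.04 FPKM.

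Of 77 P450 genes, 14 were lower and 1 higher, or 17 and 1 adjusted over the list alone. Cyp6w1 fell from 210.86 ± 12.14 to 32.02 ± 10.13 FPKM and Cyp6a2 fell from 70.56 ± 13.07 to 13.67 ± 3.64 FPKM, while Cyp6a16 rose by 1.14 on the log2 scale (adjusted p 0.0575 without resistant replicate 1). Of 26 UDP-glycosyltransferases 6 were lower, with Ugt302E1 falling from 11.58 ± 1.63 to 3.15 ± 0.44 FPKM. Of 33 glutathione transferases, 1 was higher and 1 lower, and of 23 carboxylesterases, 1 was higher and 2 lower, or 1 and 0, and 0 and 3, after scaling. Of 37 ABC transporters, 2 were higher and 2 lower, or 1 and 2 after scaling, and CG4822 fell from 19.61 ± 0.64 to 7.98 ± 1.24 FPKM.

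Antimicrobial genes were lower in 23 of 41 and higher in 1, or 26 and 2 adjusted over the list alone and 25 and 0 after scaling. DptB fell from 80.11 ± 38.99 to 3.34 ± 0.26 FPKM and Mtk from 60.41 ± 22.72 to 4.48 ± 1.06 FPKM, both encoding antimicrobial peptides. PPO1 fell from 18.45 ± 0.96 to 2.87 ± 0.97 FPKM. Digestive proteases were lower in 9 of 31, or 6 after scaling, and carbohydrases in 9 of 19, where Mal-B2, a maltase, fell from 209.43 ± 51.97 to 51.71 ± 10.22 FPKM. The carbohydrase list varied widely among the resistant libraries, with a mean log2 level of 5.013 ± 0.74 against 6.146 ± 0.171 in sensitive adults. Desat1, a fatty acid desaturase, fell from 701.38 ± 101.13 to 277.21 ± 65.13 FPKM. Alp8, an alkaline phosphatase, fell from 102.49 ± 16.08 to 3.57 ± 3.76 FPKM. Its relatives Alp9 and Alp10 had log2 fold changes of -3.56 and -3.75, and scaling ended their calls (adjusted p 0.0558 and 0.06961) although the fold changes, -3.65 and -3.84, were as large.

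Of 30 adult lists, camera called 17. Cuticle, accessory gland, testis, muscle, photoreceptor, neuronal and respiratory chain genes were higher, and P450, UDP-glycosyltransferase, carboxylesterase, antimicrobial, digestive protease, carbohydrase, lipid, yolk and eggshell, hemocyte and ribosomal genes were lower. With an estimated correlation camera called 0, these 17 had adjusted p = 0.4642 to 0.773, and 1 list had an unadjusted p under 0.05. Fry called 1, the testis list. In the ribosomal list the 3 single genes called were higher, while its median was -0.13. Of the 63 named genes called in adults, 31 lost the call when at least 1 library was left out and 10 lost it after scaling. The 31 is again a lower bound, since genes such as CG10814, Cpr49Ac and sordd2 fell below the filter without some libraries and were not counted.

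**Figure D3:**
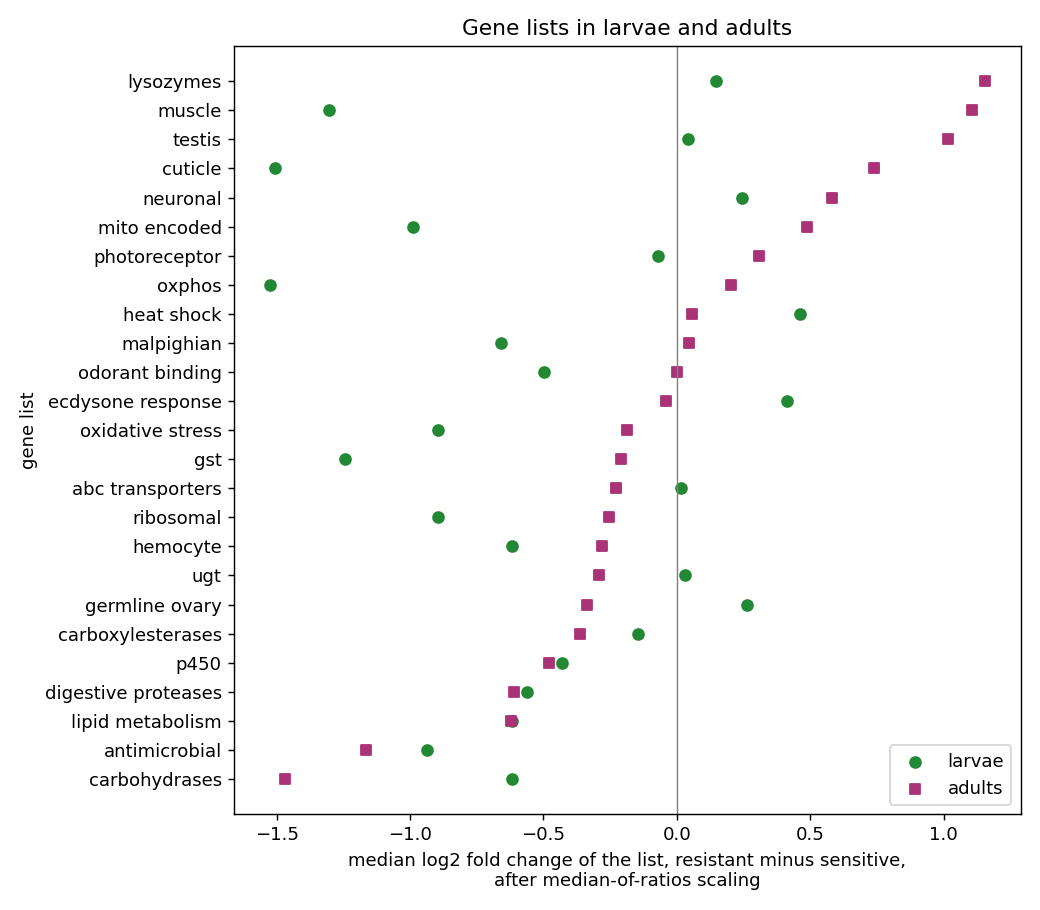
Median log2 fold change of each list with at least 5 tested members in both stages (resistant minus sensitive, after median-of-ratios scaling), circles for larvae and squares for adults. The cuticle list had medians of -1.51 in larvae and 0.74 in adults, and the muscle list -1.30 and 1.11.

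Of the 5 genes fixed for their link to avermectins, Rdl and Mdr50 in adults were called both without and with scaling. GluClalpha (3R:19730715-19775231), which encodes the glutamate-gated chloride channel that avermectins act on, was at 1.24 ± 0.19 FPKM in resistant and 0.58 ± 0.05 FPKM in sensitive larvae, with an adjusted p of 0.02417 in limma and 0.2951 after scaling, and at 2.76 ± 0.56 against 2.35 ± 0.53 FPKM in adults (adjusted p 0.7439). The larval call was lost without any of the 3 sensitive libraries (adjusted p 0.06305 to 0.06736). With any 1 of the 3 resistant libraries left out, the gene fell below the filter and was not tested, so no such fit kept the call. Rdl (3L:9145838-9182149), a GABA receptor subunit, rose in adults from 0.75 ± 0.25 to 2.02 ± 0.13 FPKM, and was too low to test in larvae. Its adult call was lost without sensitive replicate 3 (adjusted p 0.07045). With any 1 of the 3 resistant adult libraries left out, Rdl fell below the filter and was not tested. Of the P-glycoprotein transporters, Mdr50 (2R:14246966-14252597) fell in adults from 9.67 ± 2.10 to 3.59 ± 1.5 FPKM, a call lost without resistant replicate 1 (adjusted p 0.07412), and stood at 16.04 ± 1.73 against 9.80 ± 4.06 FPKM in larvae (adjusted p 0.02635, and 0.5334 after scaling), where the call was lost without any of 4 libraries (adjusted p 0.05123 to 0.1003). Mdr65 (3L:6240500-6245746) was at 5.86 ± 0.82 against 3.33 ± 0.29 FPKM in adults (adjusted p 0.04749, and 0.1356 after scaling), and the call was lost without any of the 6 libraries (adjusted p 0.05609 to 0.213). Mdr49 (2R:12940323-12946347) was not called in either stage (adjusted p 0.3814 and 0.6397), though the larval value after scaling was -0.74 (adjusted p 0.01836).

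The third comparison asked whether the strain effect differed between the stages. The cuticle genes Cpr47Eg and Cpr65Ax2 had strain effects of -7.82 and -7.35 in larvae and 0.07 and -0.77 in adults (log2), so the adult effect minus the larval one was 7.89 and 6.58. CG11350 differed by 6.98 and CG17298 by 6.55. Cpr65Ax2 and CG11350 were too low to test in adults, and CG17298 in larvae, so these differences mostly restate the effect in the other stage. Cpr47Eg was tested in adults but lay close to the filter there, so its difference also mostly restates the larval effect. In the other direction, Alp9 differed by -6.14, Alp10 by -5.63, DptB by -5.35 and gammaTry by -4.71. In limma, 3640 of 12270 genes passed, 1224 with the adult effect above the larval one and 2416 below. The median difference was -0.30, and after median-of-ratios scaling 2874 passed, 1910 above and 964 below. The calls of Cpr47Eg and Cpr65Ax2 were lost without any of 9 and 8 of the 12 libraries (adjusted p 0.05965 to 0.08855 and 0.0501 to 0.07106), and that of Cpr47Eg also with a replicate block (0.05513). In the muscle list 21 of 25 members and in the respiratory chain list 49 of 86 were called with the adult effect above the larval one, and 0 were called below it. Camera called 11 of 31 lists, all with the adult effect above the larval one: glutathione transferase, oxidative stress, cuticle, accessory gland, testis, muscle, photoreceptor, odorant-binding, ribosomal, respiratory chain and mitochondrially encoded genes. With an estimated correlation it called 0, the smallest adjusted p was 0.411 and 3 lists had an unadjusted p under 0.05, and fry called 10. Of these, 7 had the adult effect above the larval one (glutathione transferase, oxidative stress, cuticle, accessory gland, testis, muscle and respiratory chain) and 3 below it: UDP-glycosyltransferases, carboxylesterases and ABC transporters (adjusted p 0.03098, 0.01169 and 0.01169). Fry was run without scaling, the medians of these 3 went from -0.51, -0.41 and -0.62 to -0.20, -0.06 and -0.23 after scaling, and camera called none of them (adjusted p 0.05912, 0.2983 and 0.1237). The photoreceptor call was lost after scaling (adjusted p 0.1835), and 0 of its 20 members were called singly. Only 1 of 31 accessory gland and 7 of 20 photoreceptor genes passed the filter of the larval fit. The mean log2 level of the accessory gland list was 0.142 in resistant and 0.318 in sensitive larvae, so its difference largely restates the adult effect. That of the photoreceptor list was 0.962 and 0.82, so most of its members could show little larval effect.

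Across the 10473 genes tested in both stages, the strain effects of larvae and adults correlated with r of -0.021 (Pearson) and rho of -0.063 (Spearman) across genes, which are not independent replicates. Genes lower in both stages numbered 94, where 36.6 are expected of independent lists (one-sided Fisher's exact test, p 1.85e-18). Genes higher in both numbered 696, where 775.6 are expected (p 1). After median-of-ratios scaling, 133 were lower in both against 75.5 expected (p 2.30e-12) and 61 were higher in both against 120.4 (p 1). The test was for an excess only, so it cannot show the shortfall of genes higher in both. Without scaling, 126 genes were higher in larvae and lower in adults (194.3 expected), and 117 were the reverse (146 expected). With scaling these numbered 39 (44.7 expected) and 117 (203.3 expected). The genes lower in both stages included AttC, at 7.76 ± 1.58 against 63.24 ± 20.19 FPKM in adults, TotC, a stress-induced secreted protein, at 66.74 ± 33.99 against 350.21 ± 112.33 FPKM in adults, Gnmt, glycine N-methyltransferase, at 22.75 ± 16.28 against 149.72 ± 46.93 FPKM in adults, and CG10814. The gene sordd2 (X:15796908-15799162) was listed at 0 in all 6 resistant libraries and at 2.63 to 7.69 FPKM in all 6 sensitive ones. Higher in both were Cpr49Ac, Mmp1, a matrix metalloproteinase, CG13856 and Sclp. The adult call of Mmp1 was lost without sensitive replicate 2 or 3 (adjusted p 0.0577 and 0.07003). Sclp was at 177.21 ± 22.46 against 37.03 ± 12.98 FPKM in adults.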

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

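The tests on developmental age, adult age, carried-over larval tissue, male share and transcript length were chosen after the results were seen; the comparisons with other groupings of the libraries were not.

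The strain effect differed between adults and larvae, by the limma test of the difference itself, for 3640 genes. That fit was without scaling, and its median difference was -0.30. After median-of-ratios scaling, 1179 of the 1224 positive calls but only 961 of the 2416 negative calls were kept. Part of the negative values below may therefore not hold after scaling. The adult effect minus the larval effect, in log2 units, was positive among the named genes for Cpr47Eg 7.89, CG11350 6.98, Cpr65Ax2 6.58, CG17298 6.55, CG17105 6.18, PGRP-SC1a 5.99, Fbp2 5.85, Lcp65Ag3 5.74, Obp83g 5.63, Lcp65Ae 5.47, GstD2 5.01, TpnC47D 4.89, Cpr64Aa 4.66, Mlp60A 4.57, CG42323 4.52, CG34205 4.26, GstD7 4.13, Fbp1 4.08, PGRP-SC1b 3.79, Obp56e 3.44, UQCR-Q 2.30, TpnC41C 2.29, Sfp96F 2.16, Est-6 2.09, ATPsynF 2.02, Ugt35B1 1.94, Pgd 1.90, tobi 1.85, Cyp6a16 1.83, Acp53C14c 1.80, apolpp 1.66, GstE9 1.55, CG10814 1.48, alpha-Est2 1.44, Jhe 1.40, Cyp6a8 1.33, GstS1 1.33, mt:ND3 1.31, st 1.15, Uro 1.12, Men 1.11, CG9270 1.04, AttC 1.02, RpS19b 0.97, ProtA 0.94, RpL17 0.84, Oatp58Dc 0.79, AcCoAS 0.70. It was negative for Alp9 -6.14, Alp10 -5.63, DptB -5.35, gammaTry -4.71, CG6839 -4.27, CG3819 -4.24, CR31054 -4.09, alphaTry -3.31, CG7248 -3.15, BomS6 -3.01, Mtk -2.83, LManI -2.77, CG8492 -2.64, Jon65Aiv -2.63, CG4822 -2.61, Alp8 -2.60, Nrt -2.34, CG4757 -2.28, Cyp6w1 -2.17, Irc -1.96, Mdr50 -1.96, BomS3 -1.93, Cyp9f2 -1.90, Ugt302E1 -1.88, Mal-B2 -1.85, Est-P -1.82, Amy-d -1.82, Obp83ef -1.75, crq -1.67, Mal-A7 -1.64, Ugt302K1 -1.59, whd -1.48, Atet -1.47, Ugt36D1 -1.37, Cyp304a1 -1.35, Lip4 -1.29, Cpr76Bc -1.22, Desat1 -1.06, Sod3 -0.99. Of 100 groupings of the libraries that keep 3 against 3 in each stage, 2 gave as many genes, the real one included. The highest other count was 4437, from a grouping that kept the larval strains and mixed the adult ones. The 8 other drawn groupings that kept the larval strains gave 450 to 4437 genes and the 91 that mixed them gave 0 to 719, so the count largely reflects the larval strain difference and these splits do not test whether the effect differs between the stages.

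The larval strain comparison called 6484 genes, and the highest of the other 9 groupings of the 6 libraries called 2; the adult comparison called 2309, and the highest other called 1. In each, only the real grouping, 1 of 10, gave as many. With 10 groupings the share cannot be under 0.1, so these are too few for a test. For gene lists the larval count of 15 was reached by 6 of 10 groupings, the highest other being 16. The adult count of 17 was reached by 1 of 10, the highest other being 14. Camera with a preset correlation thus called about as many lists whichever larvae were grouped together.

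In resistant larvae 35 of 68 cuticle genes were lower and 15 higher, 14 of 23 muscle genes lower and 1 higher and 57 of 84 respiratory chain genes lower and 9 higher, but with an estimated correlation none of the 3 lists was called (adjusted p 0.2613, 0.2956 and 0.316). Transcript length was argued against as the sole source. With a trend on length removed, all 175 tested members had a median of -1.23 relative to all genes, and -1.46 before. The bootstrap interval, -1.41 to -1.03, resampled genes as if independent, with the libraries fixed. It does not measure the spread between libraries. A difference in age within the third instar may account for the pattern, but cannot be told apart from strain, because the labels give no exact age. After scaling, the ecdysone list had a median of 0.414 and was not called by camera (adjusted p 0.4436), and an earlier test, on whether resistant larvae replicate 3 lay along the strain difference, was void because deviations within a group sum to 0. A biological difference between the strains stays open and untested.

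In resistant adults 3 of 4 larval serum genes (not Lsp2) and Fbp1 and Fbp2 were higher. Carry-over of larval tissue at large was argued against as the sole source of their excess. The excess of these 6 genes, Lsp2 included, stood for a median of 0.849% of the resistant larval level (0.1765 to 2.2126%). For comparison, 14 other transcripts were taken, with means of 1000 FPKM or more in resistant larvae and under 5 FPKM in sensitive adults. The 6 genes were not held to these limits. Lsp1alpha was at 272.63 FPKM in resistant larvae, and Lsp1beta and Lsp2 at 7.74 and 68.41 FPKM in sensitive adults. The excess of the 14 stood for a median of 0.049% (bootstrap interval over genes 0.0312 to 0.0629). This lay below 0.0849%, a bound set as a fraction of the 0.849% itself, although the sets overlapped (0.0145 to 0.5854% over the 14). All 14 were higher in resistant adults, so a smaller carry-over stays open. Pupal tissue and larval fat body alone, which the 14 genes, mostly of cuticle and glue, do not track, were not tested and stay open. Younger adults in the resistant libraries may account for it, and cuticle genes were also higher, with a median of 0.738 after scaling, but the cuticle call was lost with an estimated correlation (adjusted p 0.4689), and age and strain cannot be told apart. A difference between the strains at one age stays open and untested.

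In resistant adults 24 of 27 testis and 19 of 31 accessory gland genes were higher (20 and 17 after scaling) and 0 lower, but with an estimated correlation neither list was called (adjusted p 0.4642 for both). Transcript length was argued against as the sole source. All 58 tested members kept a median of 0.989 relative to all genes with the trend removed (bootstrap interval 0.79 to 1.15). This interval too is over genes and not over libraries. A larger share of males may account for it: the 42 yolk, eggshell and ovary genes differed by -0.327 in mean log2 level, but 1 resistant library stood above all 3 sensitive ones (exact permutation p 0.4, where 0.1 is the smallest possible), and the labels give no sex. Male share and a strain difference in these tissues cannot be told apart.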

How the results depend on the processing

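The count with the 100 most abundant genes left out was chosen after seeing the data. The planned count-based tools (edgeR, DESeq2, voom) were not run, since the file holds FPKM, and a filter of 1 in 3 libraries equals the one used. The larval count of 6484 was 3355 with median-of-ratios scaling, 4138 at an FDR of 0.01 and 2010 at an absolute log2 fold change of 1 or more. Leaving the top 100 genes out, with scaling to the total of the remaining genes, gave 6826 and a median of 0.545. Common-total scaling with all genes gave 7508 and a median of 0.642, so leaving them out lowered the larval shift but did not remove it. The adult count of 2309 was 600 and 1271 at the stricter thresholds, the count for the difference between stages, 3640, was 1318 at an FDR of 0.01, and the count of genes called in both stages, 790, was 194 with median-of-ratios and 340 with upper-quartile scaling, 389 with a mean FPKM of 5 or more, 105 at an FDR of 0.01 and 99 at a log2 fold change of 1 or more. The larval share of higher calls was 2762 of 4361 with upper-quartile and 6610 of 7508 with common-total scaling. Where a stricter threshold did not set a count, the cause was not tested. With a library left out the counts ranged from 4958 to 6126 in larvae, from 497 to 2282 in adults, from 2117 to 4730 for the difference and from 167 to 830 for both stages; the lowest count for both stages came without adult resistant replicate 1. The difference was 2117 without larva sensitive replicate 3, 2315 without larva resistant replicate 1 and 2389 without adult resistant replicate 1; both stages gave 418 and 289 without adult sensitive replicates 2 and 3. Camera called 13 to 15 larval and 15 to 17 adult lists in those fits, and 0 in each stage with an estimated correlation; fry called 1 adult list. GstO1 in larvae reversed to -0.0992 with median-of-ratios scaling. Of the values for named genes, 191 lost the call with a library left out and 91 under other settings. A gene below the filter of a fit had no value there and was not counted. Same-numbered samples of a stage did not deviate together (correlations of -0.2 to 0.2); across stages, resistant larvae and sensitive adults did (0.18 to 0.52) but the other pairs ranged from -0.26 to 0.16, so the numbers were not taken to pair them; with a replicate block the counts were 6102, 2438, 3054 and 738, with 14 larval and 16 adult lists, and the block ended the larval calls of Amy-d, CG3819, CG6839, Cpr47Eg, GstO1 and RpL10Aa, the adult ones of CG17298, CG42323, Cpr64Ac, Jhe and Mdr65, and that of Cpr47Eg for the difference. The block also ended the camera calls of larval digestive proteases (adjusted p 0.05866) and of adult photoreceptor and ribosomal genes (0.09547 and 0.06256). It added a camera call of the adult ecdysone list (0.02464). Without larva resistant replicate 3, which lay apart from its group, the larval count was 5873, and without adult sensitive replicate 1 the adult count was 2061. The estimated depth of 11220000 to 12180000 reads limits genes near 1 FPKM.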

Other observations

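The comparison of neighbouring genes with larva-only sets was set before its result was seen; the removal of family members and overlapping pairs was added after.

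The counts of the remaining lists were as follows. Heat shock genes were higher in 11 and lower in 1 of 19 in larvae, or 4 and 2 after scaling, and higher in 5 of 21 in adults, or 3 after scaling. Lysozymes were lower in 1 of 7 in larvae, and in adults 4 of 7 were higher and 1 lower. Ligand-gated chloride channels were higher in 3 of 4 tested in larvae, or 0 after scaling, and in adults 1 of 8 was higher and 1 lower. Nicotinic receptors were higher in 2 of 3 in larvae, which turned to 1 lower after scaling, and in 0 of 5 in adults. Chemoreceptors were higher in 1 of 3 in larvae, which turned to 1 lower after scaling, and in 2 of 8 in adults, or 1 after scaling. In adults, 8 of 33 odorant-binding, 4 of 22 ecdysone, 1 of 15 Malpighian, 1 of 13 mitochondrially encoded and 0 of 4 salivary glue genes were higher, or 4, 3, 1, 0 and 0 after scaling. In larvae, 5 of 8 female germline, 17 of 27 testis, 4 of 10 neuronal and 1 of 7 photoreceptor genes were higher; after scaling these were 2, 1, 2 and 0, with 0, 1, 1 and 0 lower, and the testis median was 0.04. Members of the larval lists called lower numbered 8 of 23 for oxidative stress, 6 of 22 for lipid metabolism, 4 of 12 for hemocyte, 8 of 21 for odorant-binding, 3 of 13 for Malpighian, 20 of 86 for ribosomal and 1 of 13 for mitochondrially encoded genes, with 4, 2, 3, 2, 3, 1 and 0 higher. After scaling, 14, 11, 6, 10, 8, 58 and 8 were lower and 0, 0, 1, 1, 0, 0 and 0 higher. Adjusted over the list alone, 0 ribosomal and 0 mitochondrially encoded genes were called. Digestive proteases had 5 higher and 2 lower of 28 in larvae and carbohydrases 4 and 3 of 18, which turned to 2 and 4, and 1 and 3, after scaling. In adults, oxidative stress genes had 2 higher and 1 lower of 23, lipid genes 4 lower of 22, hemocyte genes 3 lower of 12 and ribosomal genes 3 higher of 87. Of 3 yolk and eggshell genes tested in larvae, 1 was higher and 2 lower. Of the larval serum genes, 3 of 4 were lower in larvae. The dosage compensation list had 1 gene in the file, higher in larvae but not called there after scaling, and not called in adults. The 1 accessory gland gene tested in larvae was not called, and was lower after scaling.

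Sensitive larvae had Yp3, a yolk protein gene, at 132.33 ± 24.03 FPKM and resistant larvae at 5.84 ± 1.09 FPKM (log2 fold change -4.28, adjusted p 9.92e-07 in limma), and Lsp1alpha, a larval serum gene, at 3539.74 ± 821.06 against 272.63 ± 44.64 FPKM (log2 fold change -3.68, adjusted p 1.45e-05). Both were chosen after their values were seen.

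The genes called in both stages in the same direction numbered 790, and the highest of the other 99 groupings drawn gave 0, so 1 of 100 splits gave as many. Mixing the strains left at most 2 calls in larvae and 1 in adults, so no other drawn split could give more than 2 and the comparison says nothing on the overlap. The split that kept the strains apart in both stages but reversed the adult labels was not drawn. After scaling, 60 genes higher and 131 lower in both stages lay on the main chromosomes, and 18 adjacent pairs changed the same way, all 18 lower. Random sets of the same size from genes called in larvae alone gave 2.8 pairs on average and at most 10 (share 1e-04, the smallest that 10000 draws can give). A hypothesis is that the strains may differ in blocks of the genome that hold neighbouring genes. However, 13 of the pairs shared the start of their name or had no family name, such as Cyp4ac1 and Cyp4ac2, AttA and AttB, and TotA and TotC, and 1 pair overlapped. With those removed, 4 pairs were left, where such sets gave 1.4 on average (share 0.0543). Blocks of the genome therefore cannot be told apart from tandem copies that share reads or regulation. The pair of CR44383 and sordd2 lies on X, 15796477 to 15799162.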
